A study of Homo sapiens with 6 samples.

How the data were processed

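Total RNA from 6 samples of human foot skin, 3 diabetic without ulcer or neuropathy and 3 healthy non-diabetic, was measured on 6 single-colour Affymetrix Human Gene 2.0 ST arrays. Per the labels, RNA with an integrity number above 5 was used, from 100 to 300 ng were reverse transcribed and amplified, and biotin-labelled cDNA was hybridised. Per the labels and the submitters' processing notes, the authors normalized and summarized the scanner files per gene in Affymetrix Expression Console and compared the groups in Transcriptome Analysis Console 2.0. The background method, the version of Expression Console and the genome build are not given in the sources used here. The values deposited by the authors were read as log2 expression, since they ran from 1.14 to 14.3 with array medians between 5.702 and 5.734. The log base itself is not stated in the labels, so a fold given here assumes base 2. Normalization made the 6 distributions nearly equal, so a shift shared by most genes would not be seen, and no background or detection value was used to set a lower limit of signal.

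The table held 53617 probe sets. The platform annotation paired 16098 of them with 1 gene symbol and 0 with several, and the remaining 37519 were not named and were used only in an alternative fit. The named probe sets covered 11916 of the 20056 protein-coding genes of the GRCh38.p14 annotation, which was used for current symbols and gene order only, so several well-known members of the lists were not analysed here. Because the samples came from people, 12 probe sets of Y-linked genes and of X inactivation transcripts were left out, which left 16086 probe sets of 14873 genes. For the 778 genes with several probe sets, the one with the highest mean over the 6 arrays stood for the gene. 3 older symbols in the lists that several genes share were read as the gene that once held them officially, a step added after the data were seen.

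The labels gave the group and the replicate number of each sample. They do not state that the samples came from separate donors, so p-values measure only the spread between these samples, which may be technical. At most 0.0541% of values were identical between any pair of arrays, so no array was a copy of another. Samples with the same number deviated together from their group means, with correlations across probe sets of 0.121, 0.182 and 0.243, and all exceeded the limit of 0.1 set for treating the numbers as pairs. Samples with different numbers were not compared in this check. Deviations cancel out within a group, so some matching of the arrays tends to correlate positively whatever the numbers mean. The check alone does not show that the numbers mark pairs. The pairing comes from the numbers in the labels and this check, not from a stated shared donor or day, and the groups are different people. The fit without the block was the main result, and the fit with the replicate number as a block is given where it changed a call.

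Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, diabetic minus non-diabetic, no covariate), with Benjamini-Hochberg adjustment over the probe sets tested and calls at an adjusted p under 0.05. The moderated variances had 3.83 prior degrees of freedom. The threshold in the series' design text, an unadjusted p under 0.05 and a change over 2-fold, was applied to the same fit, since the test behind it is not given in the sources used here. The 29 gene lists, their tests, the alternatives and the rule for named genes were set before the data were examined. Lists were tested with limma's camera at a preset correlation of 0.01 and adjusted over the 29 lists, with camera at an estimated correlation and fry as alternatives. An SE given with the log2 difference of a gene is the moderated SE of the limma fit. It borrows from the variances of all probe sets tested, so it can differ from the SE of the gene's own arrays. The 95% intervals are those of the limma fit or, for list means, of the difference between groups. They do not use the replicate numbers as pairs.

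Genes were named by rule. Up to 12 per direction past an adjusted p of 0.05 came first, with places filled by genes at an unadjusted p under 0.05, over 2-fold and with no overlap between groups, by size, and up to 4 members per list with the smallest p were added. No place was filled by an adjusted p, and 14 higher and 11 lower genes met the second part, of which 12 and 7 were named after the exclusions below and the limit of 12. Genes with common whole-gene deletions, immune receptor and HLA genes, olfactory receptors, loci without a gene name and small RNAs were not named. List members named outside this rule were chosen after their values were seen, and these are HBEGF, S100A12, IL1RN, FLG, LORICRIN, KRT10 and KRT9.

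The fit was tested on simulated data with the variances fitted to the 16086 probe sets, 3 arrays against 3, over 10 runs with 200 changed genes each. It found 70.1% of genes changed by 1 and 97.2% of genes changed by 2 on the log2 scale, with 9.3 false calls per run. The changed genes were picked at random, their variances were drawn from the fitted prior, and errors were independent. These shares therefore do not give the power of the real comparison, where a missing call is not evidence of no change. In 20 simulated lists of 20 genes shifted by 0.5, camera found 20, and it called 0 of 560 unchanged lists, with genes that varied independently. Genes of the real lists that passed had estimated correlations from 0.112 to 0.662, so the simulated lists do not show how often camera errs on them. The alternatives were another variance prior, no moderation, a second normalization, centring, a filter on dim probe sets, all probe sets, other rules for several probe sets per gene, array weights, the replicate block, other thresholds and list tests, and leaving out each array in turn. No labels gave a batch, and figures were drawn with matplotlib 3.10.9.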

Results

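Whole foot skin was profiled on 6 Affymetrix Human Gene 2.0 ST arrays, which measure the RNA of annotated genes with groups of short probes called probe sets. 3 arrays carried skin from the feet of people with diabetes that had neither an ulcer nor neuropathy, and 3 carried healthy foot skin of people without diabetes. The comparison asked how gene expression in diabetic foot skin differed from that in non-diabetic foot skin before any wound was present. The array medians lay between 5.702 and 5.734 on the log2 scale, and every pair of arrays correlated at an r between 0.970 and 0.983 across probe sets, which are not independent replicates. The precision was limited by the number of arrays, 3 per group.

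Among genes at an unadjusted p under 0.05, over 2-fold and with no overlap between the groups that could be named under the rule used here, the largest mean differences upward in diabetic skin were in KRT6C, S100A8, S100A9, S100A7 and KRT16. S100A8 (probe set 16693414) and S100A9 (16671139), the subunits of the calcium-binding protein calprotectin, had means 7.25-fold and 6.39-fold higher in diabetic skin, log2 differences of 2.86 ± 0.78 and 2.68 ± 0.44 (SE, n = 3 per group). S100A7 (16693427), the antimicrobial protein psoriasin, was 4.82-fold higher at 2.27 ± 0.82, and KRT16 (16844817), a keratin induced in activated keratinocytes, was 4.75-fold higher at 2.25 ± 0.43. Each SE here is moderated by limma, and the SD of S100A7 itself was 0.38 in diabetic and 1.94 in non-diabetic arrays. KRT6C (16764907), a keratin of wounded and of sole epidermis, differed by 3.26 ± 1.14, but its non-diabetic mean of 3.74 lay far below the array medians, where signal and background cannot be separated here, so the size of the difference is uncertain and no fold is given. The largest differences downward were in WIF1 (16767081), a secreted inhibitor of Wnt proteins, at −2.57 ± 0.65, whose diabetic mean of 4.84 also lay below the array medians so that no fold is given, and in LGR5 (16754134), a receptor for R-spondins that strengthens Wnt signalling, with a mean 3.83-fold lower at −1.94 ± 0.39. In diabetic replicates 1 and 3 LGR5 stood at 5.626 and 5.633, below the array medians, so its fold is uncertain. No gene passed an adjusted p of 0.05 in limma. The lowest adjusted p was 0.559, held by S100A9 and by GSTM5.

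The other genes named by size had smaller differences, and none of them passed an adjusted p of 0.05. The late cornified envelope genes LCE3E and LCE3D differed by 1.46 ± 0.40 and 1.26 ± 0.44 (log2, SE, n = 3 per group), and the diabetic mean of LCE3D, 13.2, was close to the highest array value of 14.34, where a difference can be compressed. SPRR1B and IVL, whose proteins are cross-linked into the cornified envelope, differed by 1.44 ± 0.30 and 1.07 ± 0.35. FETUB, a secreted protein of the cystatin family, differed by 1.21 ± 0.35, XDH, an enzyme of purine breakdown, by 1.12 ± 0.26, and GDPD3, a lysophospholipase, by 1.02 ± 0.19. On the lower side, the glutathione transferase GSTM5 differed by −1.60 ± 0.23, FNDC1, a protein with fibronectin domains, by −1.40 ± 0.33, and the matrix glycoprotein THBS4 by −1.35 ± 0.49. The mast cell tryptase TPSB2 differed by −1.29 ± 0.30 and NRN1, which promotes neurite growth, by −1.01 ± 0.21. The adjusted p of these genes ranged from 0.559 to 0.736, and the arrays of the groups did not overlap for any of them. Values of KRT6C, KRT16, S100A7 and of the LCE3, SPRR, GSTM and tryptase genes are uncertain, because these families hold near-identical members that probes can share. Without diabetic replicate 1, KRT6C was at 1.72 and IVL at 0.65, without non-diabetic replicate 3, S100A7 was at 1.22 and THBS4 at −0.74, and without non-diabetic replicate 1, LCE3E was at 0.96 and LCE3D at 0.72.

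**Figure D1:**
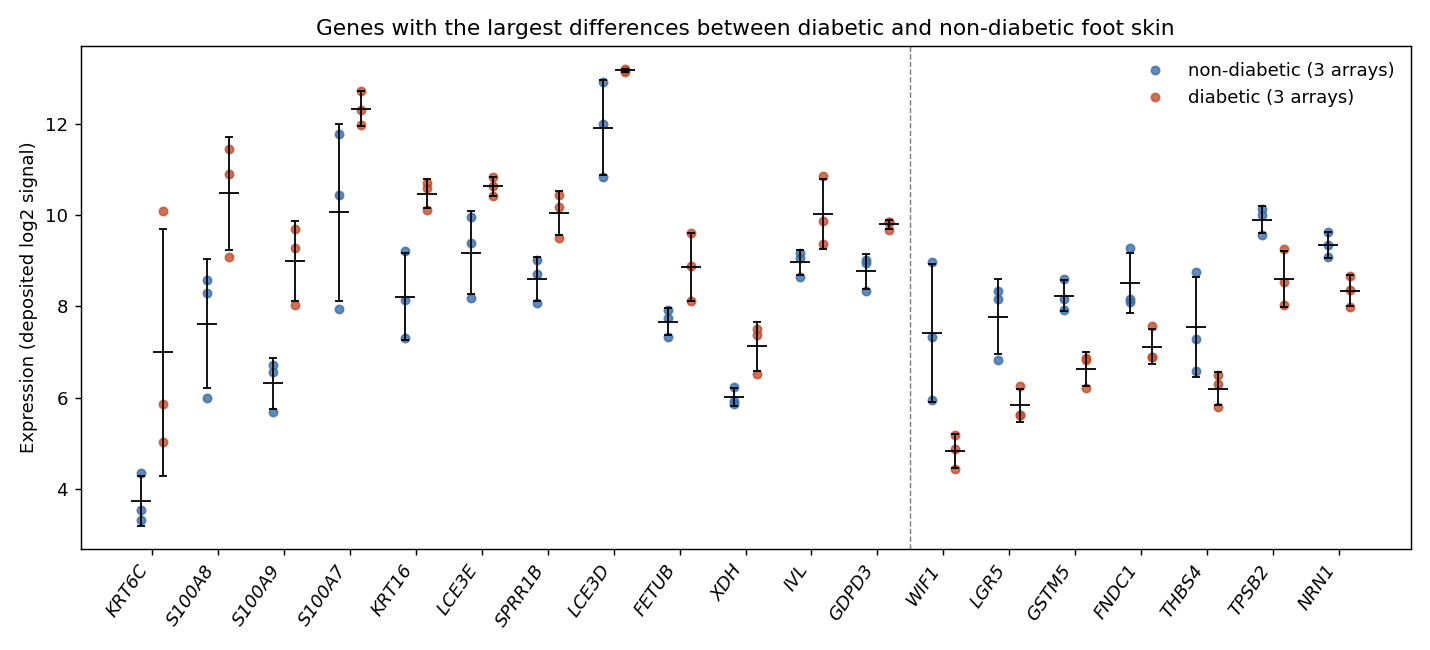
Deposited log2 expression of the 12 genes with the largest differences upward and the 7 with the largest downward that could be named under the rule, among those at an unadjusted p under 0.05, over 2-fold and with no overlap between the groups, for 3 diabetic and 3 non-diabetic arrays, with the gene on the horizontal axis. Points are arrays and bars are the mean and SD. The diabetic arrays of KRT6C spread most, with an SD of 2.71.

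Genes that keratinocytes switch on in wounds ranked higher in diabetic skin as a group. Of the 8 wound-activated keratinocyte genes measured, 8 had a higher mean in diabetic skin, with a median log2 difference of 2.26. Per array the mean of the list was 8.82 ± 0.68 in diabetic skin and 7.04 ± 0.57 in non-diabetic skin (log2, SD, n = 3 per group). The list passed limma's camera test at an adjusted p of 4.35e-07 with a preset correlation between genes, and was lost at an adjusted p = 0.464 with an estimated correlation. KRT6C, KRT16, S100A7, S100A8 and S100A9 made up the 5 members past an adjusted p of 0.05 when adjusted over the list alone, against 0 over all genes tested, and the value of KRT6C rests on the low signal given above. The remaining members were HBEGF, a growth factor of the EGF family, at 0.71 ± 0.61, the calcium-binding S100A12 at 0.11 ± 0.14, with both means below the array medians, and the interleukin-1 receptor antagonist IL1RN at 0.084 ± 0.15. Without diabetic replicate 1, HBEGF turned to −0.084 and IL1RN to −0.027, and IL1RN was also at −0.0078 without non-diabetic replicate 2. With all arrays, the differences of S100A12 and IL1RN were no larger than their SE. An exact permutation test of the list means, two-sided over the 10 splits of the arrays and added after the data were seen, gave p = 0.1, the smallest that 3 arrays against 3 allow.

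The cornified envelope and late differentiation list, the proteins that build the dead outer layer of the epidermis, also ranked higher in diabetic skin. Of its 28 measured genes 25 had a higher mean, with a median log2 difference of 0.25, and the adjusted p was 2.18e-06 in camera and adjusted p = 0.632 with an estimated correlation. SPRR1A stood at 2.21 ± 0.62 (SE, n = 3 per group), SPRR1B at 1.44 ± 0.30 and CNFN, a component of the envelope, at 0.57 ± 0.18. FLG, LORICRIN and KRT10, abundant proteins of the upper epidermis, stood at 0.11 ± 0.12, 0.14 ± 0.17 and 0.032 ± 0.12. Their diabetic means of 13.6, 13.3 and 13.9 were close to that highest array value, and none of these 3 differences was larger than its moderated SE. LCE5A went the other way at −0.95 ± 0.22. A set of 20 general keratinocyte genes, added after the data were seen, moved with the list, with 16 members higher and a median of 0.15. Adjusted over the list alone, 2 members passed, SPRR1B and LCE5A, against 0 over all genes. Without non-diabetic replicate 3 the median was 0.15 and the list was still past the threshold, at an adjusted p of 7.72e-04.

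Barrier lipid synthesis genes, which make the sterols, fatty acids and ceramides of the skin barrier, ranked higher in diabetic skin with 12 of 13 measured members at a higher mean. The median log2 difference was 0.41, with an adjusted p of 1.57e-07 in camera and adjusted p = 0.632 with an estimated correlation. The enzymes of sterol synthesis SQLE and HMGCS1 stood at 0.81 ± 0.20 and 0.57 ± 0.15 (SE, n = 3 per group), INSIG1, a regulator of the same pathway, at 0.46 ± 0.11, and the fatty acid elongase ELOVL7 at 0.49 ± 0.16. SQLE, HMGCS1 and INSIG1 were the 3 members that passed when adjusted over the list alone, against 0 over all genes. The 20 general keratinocyte genes, with 16 higher and a median of 0.15, moved with this list too. Without diabetic replicate 1 the median was 0.27, at an adjusted p of 2.76e-05.

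Oxidative stress response genes ranked higher in diabetic skin, with 12 of 17 measured members at a higher mean and a median log2 difference of 0.18. The adjusted p was 0.00141 in camera and adjusted p = 0.632 with an estimated correlation. HMOX1, which breaks down heme, stood at 0.69 ± 0.23 (SE, n = 3 per group), the glutathione peroxidase GPX2 at 0.57 ± 0.19, SRXN1, which repairs peroxiredoxins, at 0.51 ± 0.13 and the thioredoxin reductase TXNRD1 at 0.45 ± 0.19. No member passed when adjusted over the list alone or over all genes. The median moved between 0.083 without non-diabetic replicate 1, 0.085 without diabetic replicate 3, 0.28 without non-diabetic replicate 3 and 0.35 without diabetic replicate 2, with the list past the threshold each time.

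Genes of the dermal matrix ranked lower in diabetic skin. The collagens and matrix assembly list had 11 measured members, none of them a collagen chain, and 10 of the 11 had a lower mean, with a median log2 difference of −0.59. FBN1, the fibrillin of elastic microfibrils, stood at −1.15 ± 0.49 (SE, n = 3 per group), the proteoglycan LUM at −0.83 ± 0.26, LOX, which cross-links collagen and elastin, at −0.79 ± 0.32 and elastin itself, ELN, at −0.60 ± 0.30. The adjusted p was 9.06e-04 in camera and adjusted p = 0.633 with an estimated correlation. No member passed when adjusted over the list alone or over all genes. Without diabetic replicate 2 the list was lost at a median of −0.33 and an adjusted p of 0.255. Without non-diabetic replicate 3 the median was −0.28 at an adjusted p of 0.0498, with FBN1 at −0.60, LOX at −0.40 and ELN at −0.28, while without non-diabetic replicate 2 ELN was at −0.95.

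Mast cell markers ranked lower in diabetic skin together with the matrix genes. Of the 8 measured markers 8 had a lower mean, with a median log2 difference of −0.44, an adjusted p of 9.06e-04 in camera and adjusted p = 0.633 with an estimated correlation. The tryptases TPSB2 and TPSAB1 stood at −1.29 ± 0.30 and −0.46 ± 0.23 (SE, n = 3 per group), HPGDS, which makes prostaglandin D, at −1.03 ± 0.38 and HDC, which makes histamine, at −0.42 ± 0.27. TPSB2 was the 1 member that passed when adjusted over the list alone, against 0 over all genes. Without diabetic replicate 2 the list was lost, at a median of −0.096 and an adjusted p of 0.255, with TPSAB1 at −0.19 and HDC at −0.13, while without diabetic replicate 1 TPSAB1 was at −0.70 and without diabetic replicate 3 HDC was at −0.67. The diabetic means of TPSAB1 and HDC, 5.49 and 5.64, lay below the array medians, so the sizes of their differences are uncertain.

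**Figure D2:**
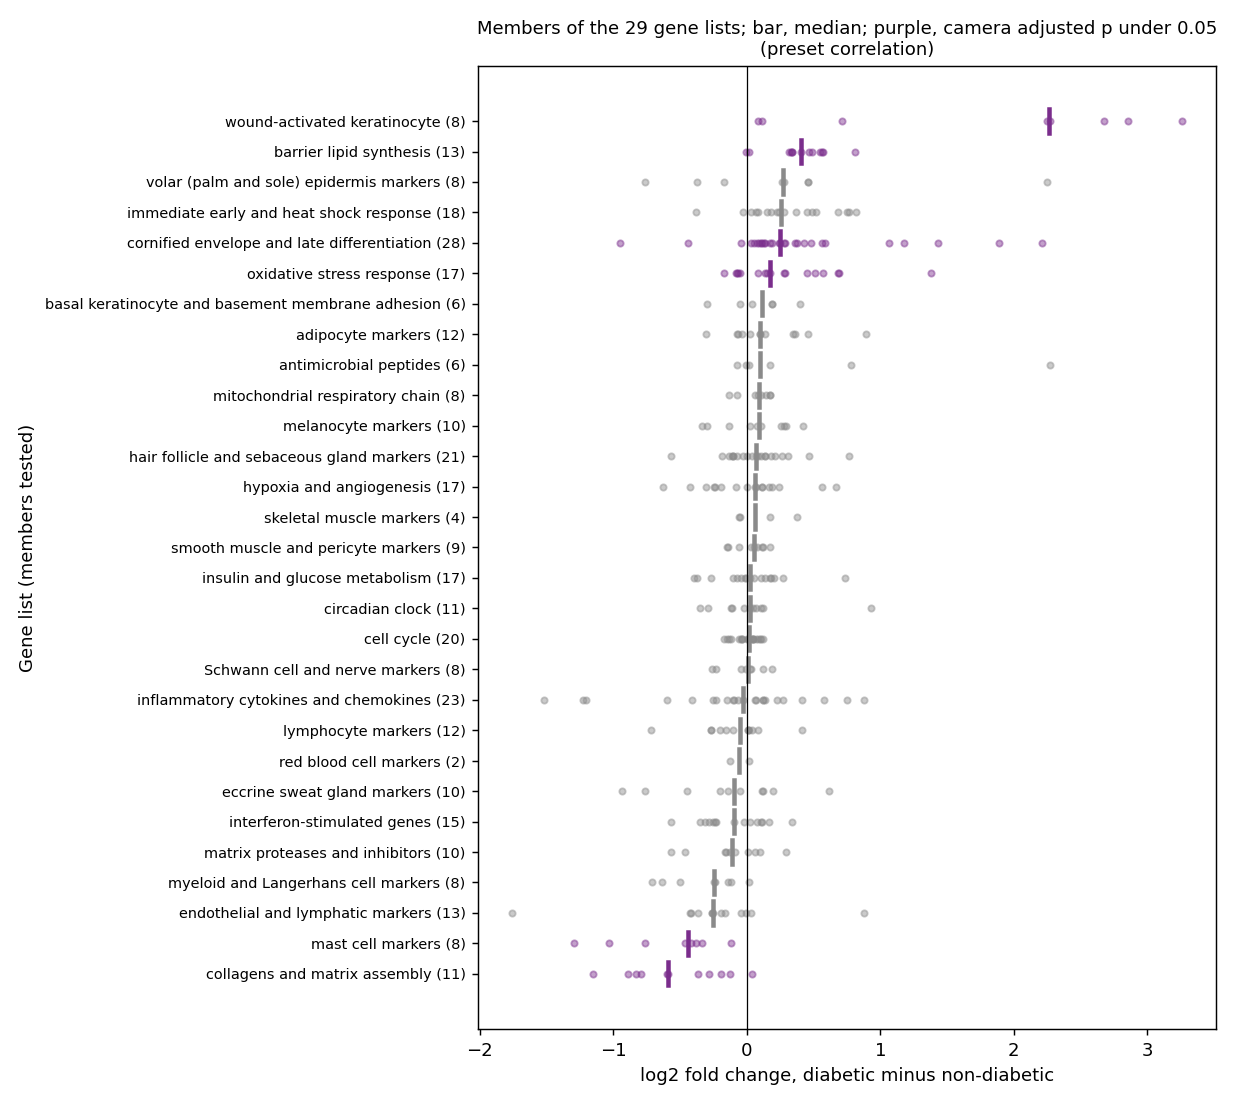
Log2 fold change, diabetic minus non-diabetic, of each measured member of the 29 gene lists, with the number of members in brackets. Points are genes, bars are list medians, and the 6 lists in purple passed an adjusted p of 0.05 in camera with a preset correlation. The wound-activated keratinocyte median of 2.26 lies farthest from 0.

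**Figure D3:**
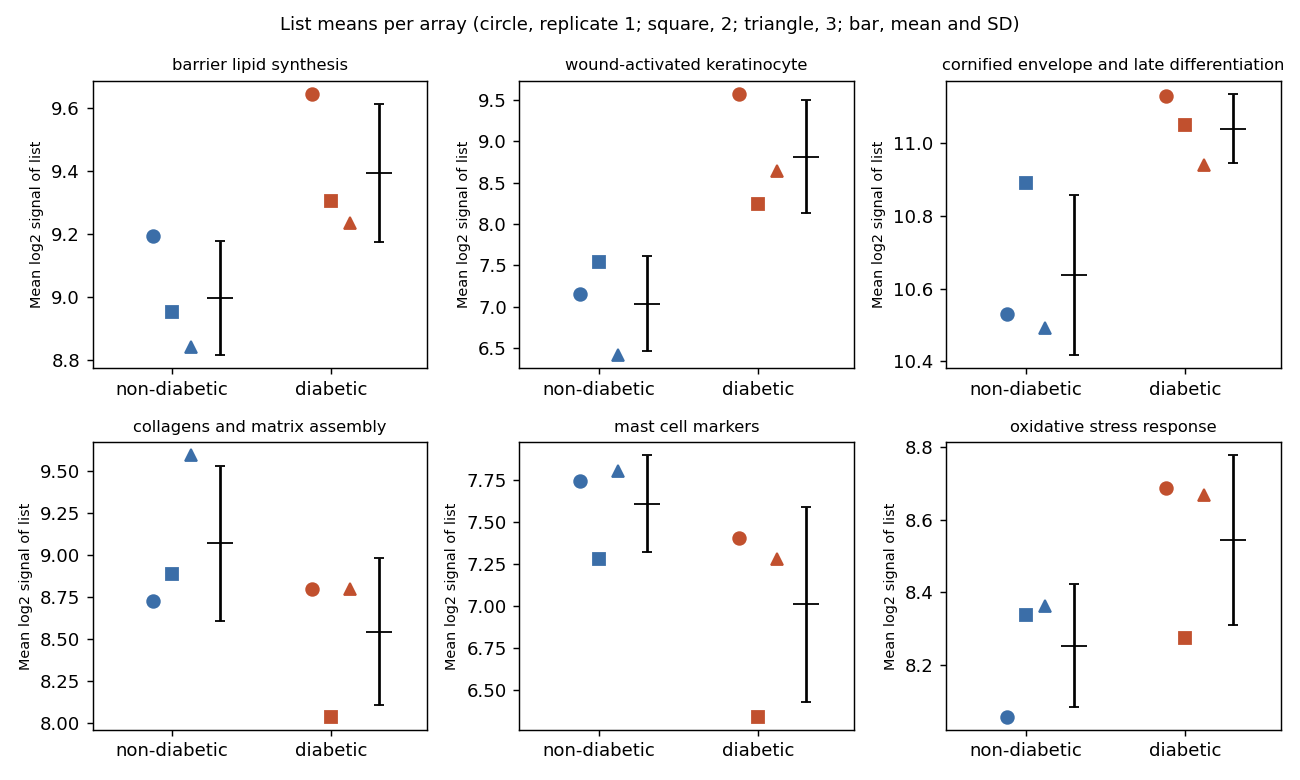
Mean log2 signal of the 6 lists that passed camera with a preset correlation, 1 point per array (3 diabetic, 3 non-diabetic), with the group mean and SD. The groups do not overlap for the wound-activated, barrier lipid and cornified envelope lists, and overlap for the other 3.

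Markers of vessels and of myeloid cells had lower means in diabetic skin without passing the test. Of 13 endothelial and lymphatic markers 11 had a lower mean, with a median log2 difference of −0.26 and an adjusted p of 0.0819, which became 0.0174 with the replicate number as a block. The median was −0.032 with an upward test at an adjusted p of 0.884 without diabetic replicate 2, and −0.46 at an adjusted p of 7.34e-04 without diabetic replicate 3. The list also passed without diabetic replicate 1 and without non-diabetic replicate 1, at an adjusted p of 0.0283 and 0.0284. LYVE1, a hyaluronan receptor of lymphatic vessels, stood at −1.76 ± 0.79 (SE, n = 3 per group), or −1.09 without non-diabetic replicate 3, and the VEGF receptor KDR at −0.43 ± 0.19, or −0.22 without diabetic replicate 2. Of 8 myeloid and Langerhans cell markers 7 had a lower mean, with a median of −0.24 and an adjusted p of 0.0819, or 0.00646 with the block. The median was −0.020 without non-diabetic replicate 3 and −0.11 without diabetic replicate 2, at an adjusted p of 0.555 and 0.527. It was −0.61 without diabetic replicate 3 and −0.60 without non-diabetic replicate 1, at an adjusted p of 0.00351 and 0.00656, and the list also passed at 0.0378 without non-diabetic replicate 2. CSF1R, the receptor for the macrophage growth factor, stood at −0.50 ± 0.19, or −0.30 without non-diabetic replicate 3, and CD1A, an antigen-presenting protein of Langerhans cells, at −0.71 ± 0.33, or −0.38 without non-diabetic replicate 1. Lymphocyte markers had a median of −0.051 with 6 of 12 members lower and an adjusted p of 0.624. Immediate early and heat shock genes, which also respond to the handling of tissue, had a higher mean for 16 of 18 members, with a median of 0.26 and an adjusted p of 0.0819, or 9.18e-07 with the block. In camera run on ranks the adjusted p of these genes was 0.0184. Without diabetic replicate 1 the direction turned, with a median of −0.17 and an adjusted p of 0.178, and without non-diabetic replicate 3 the median was 0.12 at an adjusted p of 0.454. The list passed without diabetic replicate 2, diabetic replicate 3 or non-diabetic replicate 1, with medians of 0.48, 0.37 and 0.47 and an adjusted p of 4.04e-04, 0.00969 and 7.71e-04. The heat shock gene HSPH1 stood at −0.38 ± 0.17, against the direction of the list. For the vessel, myeloid and immediate early lists, the adjusted p with an estimated correlation was 0.89, 0.746 and 0.942 in that order.

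Markers of skin site, appendages and other tissue layers did not pass the test with all 6 arrays. The volar list, genes of palm and sole epidermis, had 5 of 8 members higher, a median of 0.27 and an adjusted p of 0.324, with KRT16 past the threshold when adjusted over the list alone and KRT9, the keratin of sole and palm, at 0.46 ± 1.18 (SE, n = 3 per group). The volar median was 0.035 without diabetic replicate 2, 0.12 without non-diabetic replicate 1 and 0.17 without diabetic replicate 3 or non-diabetic replicate 2. KRT9 turned to −0.53 without diabetic replicate 2 and to −0.54 without non-diabetic replicate 1. Eccrine sweat gland markers had a median of −0.094 (adjusted p = 0.844), with the water channel AQP5 at 0.62 ± 0.30, or 0.25 without non-diabetic replicate 1. Hair follicle and sebaceous gland markers had a median of 0.071 (adjusted p = 0.293), and melanocyte markers of 0.0905 (adjusted p = 0.836), which turned to −0.18 without diabetic replicate 1 and was 0.29 without diabetic replicate 2. Adipocyte markers had 8 of 12 members higher, a median of 0.098 and an adjusted p of 0.106, with the fatty acid transporter CD36 at 0.90 ± 0.25. That list passed without diabetic replicate 1, diabetic replicate 2 or non-diabetic replicate 1, at an adjusted p of 0.0219, 0.0373 and 0.0284, and had a median of −0.016 without diabetic replicate 3. With all arrays and an estimated correlation its adjusted p was 0.709. Smooth muscle and pericyte markers had a median of 0.053 (adjusted p = 0.964), skeletal muscle markers of 0.060 (adjusted p = 0.844) and red blood cell markers, with 2 members, of −0.056 (adjusted p = 0.844). Schwann cell and nerve markers had a median of 0.0075, a mean of −0.021 and a downward test at an adjusted p of 0.964. Basal keratinocyte and basement membrane genes had a median of 0.11 (adjusted p = 0.844). Leaving out 1 array moved the median of each of the 23 lists that did not pass by over 1.5 times, and turned its sign for 17 of them, so the direction of those 17 stays open. The endothelial, myeloid, mitochondrial, eccrine, hair follicle and volar medians kept their sign but not their size. For the endothelial and eccrine lists the direction of the test still turned when an array was left out.

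Inflammatory, metabolic and cell growth lists did not pass the test with all 6 arrays either. Inflammatory cytokines and chemokines had a median of −0.025 and a mean of −0.098 but an upward test, at an adjusted p of 0.964. Interferon-stimulated genes had a median of −0.096 (adjusted p = 0.815), with the antiviral gene IFIT2 at −0.56 ± 0.19 (SE, n = 3 per group) and its diabetic mean of 5.65 below the array medians. They passed downward without diabetic replicate 1, with a median of −0.24 and an adjusted p of 0.0213. Antimicrobial peptides had a median of 0.096 and an adjusted p of 0.12, with lactoferrin, LTF, at 0.78 ± 0.24, or 0.505 without non-diabetic replicate 3. They passed without non-diabetic replicate 3, with a median of 0.46 and an adjusted p of 0.0321, and had a median of −0.0057 without diabetic replicate 3. Matrix proteases and inhibitors had a median of −0.11 (adjusted p = 0.836). Insulin and glucose metabolism genes had 9 of 17 members higher, a median of 0.026 and an adjusted p of 0.41, with the hexokinase HK2 at 0.73 ± 0.24, or 0.47 without non-diabetic replicate 1, and the insulin receptor substrate IRS2 at 0.27 ± 0.13. Hypoxia and angiogenesis genes had a median of 0.063 (adjusted p = 0.665), and the mitophagy receptor BNIP3, at 0.67 ± 0.15, was the 1 member past the threshold when adjusted over the list alone. The mitochondrial respiratory chain had a median of 0.093 (adjusted p = 0.307). Circadian clock genes had a median of 0.022 (adjusted p = 0.881), with PER1, a clock gene that cortisol induces, at 0.93 ± 0.31. Cell cycle genes had a median of 0.016, a mean of −0.0026 and an upward test at an adjusted p of 0.881, but passed downward without diabetic replicate 1, with a median of −0.16 and an adjusted p of 0.0448. With all arrays and an estimated correlation the adjusted p of the interferon, antimicrobial and cell cycle lists was 0.942, 0.633 and 0.978.

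Across all 16086 probe sets tested, 0 genes passed an adjusted p of 0.05, 0.10 or 0.25 in limma, while 1075 stood at an unadjusted p under 0.05, of which 433 were higher and 642 lower in diabetic skin and where 804 would be expected by chance. Without non-diabetic replicate 3 that count was 695, below the number expected by chance. The threshold in the series' own design text, an unadjusted p under 0.05 with a change over 2-fold, was met by 40 genes, 19 higher and 21 lower, of which 10 could not be named under the rule and others are left unnamed here. The arrays of the groups did not overlap for 25 of the 40, and for 11.8% of all probe sets tested, where chance gives 10%. The 2-fold count was 69 without diabetic replicate 2, 96 without diabetic replicate 3, 93 without non-diabetic replicate 1 and 72 without non-diabetic replicate 2. Of the 29 lists, 6 passed camera with a preset correlation, 4 higher and 2 lower, and 0 passed with an estimated correlation or with limma's fry test.

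The groups could not be told apart from the spread between arrays, whether same-numbered samples were kept or left out. The mean r was 0.977 within the diabetic group, 0.982 within the non-diabetic group and 0.978 between groups, so that the mean within groups exceeded the mean between groups by 0.0016. An exact permutation test, one-sided over the 10 splits, gave p = 0.2, where 0.1 is the smallest it allows. With the same-numbered pairs, whose mean r was 0.980, left out of the mean between groups, a choice made after the data were seen, the excess was 0.0028. Of the 4 splits that part all pairs the real one had the largest excess, which 4 splits cannot tell from chance, and it gave 40 genes at the 2-fold threshold against 13 to 26 in the other 3. The first principal component held 29.8% of the variance and set diabetic replicates 1 and 2, at −21.1 and −20.5, against non-diabetic replicate 3, at 26.8, with the remaining arrays between 0.713 and 9.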

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

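The test of list means and the comparison of arrays without same-numbered pairs were added after the data were seen, and IGFL1 was named after its value was seen. No alternative with all 6 arrays gave a gene past an adjusted p of 0.05, and leaving out each array in turn gave between 0 and 1 genes. The 1 gene was IGFL1, an insulin growth factor-like gene, without diabetic replicate 2, with an adjusted p of 0.0101 against 0.743 with all arrays, and its non-diabetic values of 5.31 to 5.56 lay below the array medians, so no size is given. In every other setting the lowest adjusted p of any gene was at least 0.144. Without moderation of the variances the 2-fold count of 40 became 14, all of them among the 40. Moderation leaves a difference unchanged, so the rest of the 40 met the unadjusted p limit only with moderated variances. The 2-fold count became 213 with all probe sets, where more were tested, and 240 at a looser limit of 1.5-fold. Leaving out each array in turn moved it between 43 and 96, and the cause was not tested. With the replicate number as a block it was 60, with 0 genes past an adjusted p of 0.05 and 9 lists, and the block changed no call except the immediate early, myeloid and endothelial lists. The 6 lists became 0 with an estimated correlation, which ran from 0.112 to 0.662 for these lists against the preset 0.01. The count was 0 with fry and between 6 and 10 with each array left out. It was also 0 with an exact permutation test of list means, which cannot go below p = 0.1. The wound-activated, cornified envelope and barrier lipid lists reached p = 0.1 in this exact permutation test. The exact permutation test gave p = 0.2 for the mast cell list and p = 0.3 for the matrix and oxidative stress lists. For the mast cell, matrix and oxidative stress lists, other splits of the arrays thus gave a difference at least as large. The adjusted p of the matrix list ranged from 7.33e-06 to 0.732 and that of the mast cell list from 2.92e-06 to 0.732. For the 37 named genes recomputed, 0 of 591 values turned sign and 0 passed an adjusted p of 0.05. Many of these genes, among them all those named by size, had no overlap between the groups. Leaving out an array cannot turn the sign of such a gene, and the block and the variance settings do not change a difference. The absence of turned signs is therefore no evidence of stability. Of 23 further genes named, 4 turned sign and 14 moved by over 1.5 times or turned when 1 array was left out. Of the 23 lists that did not pass, up to 11 changed direction in a setting, the most without diabetic replicate 1. With only genes above the median level, lymphocyte and red blood cell lists had under 2 members and no value. The difference of mean r within and between groups was 0.00376 for brighter probe sets, 0.00134 with Spearman's correlation and 0.00282 without same-numbered pairs.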

Other observations

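The tests of a smaller share of dermis, and those of the epidermal differentiation complex without the genes named by size and against general keratinocyte genes, were chosen after the results were seen, and the sets of general keratinocyte, Wnt and epidermal differentiation complex genes were chosen after the main comparison was seen. The epidermal differentiation complex, a run of neighbouring genes for cornified envelope and S100 proteins, had a higher mean in diabetic skin for 55 of 61 measured genes, with a median log2 difference of 0.23. A candidate explanation, that the whole complex and not only the genes of the fixed lists stood higher, was tested on its 38 genes outside those lists. Of these 33 had a higher mean, with a median of 0.22, and they ranked above other genes at a camera p of 3.09e-07 with a preset correlation and 0.0138 with an estimated correlation. The 95% interval of the difference in their mean per array ran from −0.0090 to 0.55. The camera p-values of the added sets are not adjusted. Unadjusted and with an estimated correlation, camera gave 0.016 for the wound-activated list and 0.0437 for the cornified envelope list. For the remaining lists that had passed it gave between 0.0752 and 0.175. LCE3D and LCE3E, already named by their size, were among the 38, and without them 31 of 36 had a higher mean, with a median of 0.22 and a camera p of 4.31e-06, or 0.0188 with an estimated correlation, while the 95% interval of the difference in their mean per array ran from −0.058 to 0.48. General keratinocyte genes moved the same way, with 16 of 20 higher, a median of 0.15 and a camera p of 0.00161, or 0.25 with an estimated correlation. A larger share of epidermis in the diabetic samples stays open for the complex, since these 36 genes differed from the general ones by 0.078 (−0.35 to 0.51), for the cornified envelope list, which differed from them by 0.27 (−0.081 to 0.62), and for the barrier lipid list, at 0.27 (−0.055 to 0.59) in a test added after the results were seen. These intervals are unpaired, and the differences were not tested within same-numbered pairs. S100A14 stood at 0.39 ± 0.15 (SE, n = 3 per group), chosen after its value was seen and not past an adjusted p of 0.05 in limma.

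Genes around the Wnt pathway other than WIF1 and LGR5 went both ways. The secreted Wnt-binding protein FRZB stood at −0.81 ± 0.18 and ROR1, a receptor for Wnt proteins, at 0.48 ± 0.13 (log2, SE, n = 3 per group). These genes were chosen after their values were seen and none passed an adjusted p of 0.05 in limma. Whether a lower Wnt pathway as a whole lies behind the lower WIF1 and LGR5 stays open. Of 36 other Wnt genes, 24 had a lower mean at a camera p of 0.128, with an interval of their mean difference from −0.25 to 0.015. These 36 hold receptors such as ROR1 together with secreted Wnt-binding proteins such as FRZB. A lower mean of such a mixed set does not measure lower Wnt signalling, so the test could not decide the question. A p of 0.05 or more had been set in advance as evidence against a lower pathway, which was wrong. A missed threshold leaves room for a fall within that interval.

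The higher wound-activated keratinocyte genes, with a median of 2.26, were weighed against other accounts. A larger share of epidermis in the diabetic samples was argued against as the whole cause, since the mean of these genes minus that of 20 general keratinocyte genes differed between groups by 1.64, with a 95% interval from 0.44 to 2.85, while the general genes themselves differed by 0.13 (−0.15 to 0.41). That contrast includes KRT6C, whose size is uncertain. Some general genes, such as DSP at 13.4 in both groups, lie where a difference can be compressed. The contrast was not recomputed without them. Diabetic replicate 1 alone was argued against, since the median without it was 1.92. The list means of diabetic replicates 2 and 3, 8.24 and 8.64, also lay above the non-diabetic ones, from 6.42 to 7.54. Without that array the adjusted p was 2.19e-05 in camera with a preset correlation. That p adds no weight, since the list was lost with an estimated correlation. Without non-diabetic replicate 3 the median was 1.63. More sole than other foot skin in the diabetic samples could account for part and cannot be told apart, because the interval of KRT9, from −2.27 to 3.18 around 0.46, is too wide. Diabetes, which the design names, stays open as a hypothesis and was not tested apart from other differences between the people.

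The lower dermal matrix genes may come from a smaller share of dermis in the diabetic samples. That account needs the other dermal lists (smooth muscle, nerve and lymphocytes) to fall alike, and the matrix list differed from their mean by −0.49, with a 95% interval from −1.47 to 0.48, while those lists differed by −0.031 (−0.32 to 0.25). With the mast cell, endothelial and myeloid lists added, which had lower medians, the matrix list differed from the mean of the 6 by −0.31 (−0.98 to 0.36) and the 6 lists by −0.21 (−0.73 to 0.31), so nothing was decided. Non-diabetic replicate 3 alone cannot be told apart either, since without it the median went from −0.59 to −0.28 and stayed under the adjusted p threshold at 0.0498. Diabetic replicate 2 alone stays open too, since without it the list was lost in camera, at a median of −0.33 and an adjusted p of 0.255. The mean of the matrix list was 8.04 on that array and 8.80 on diabetic replicates 1 and 3. On non-diabetic replicates 1, 2 and 3 it was 8.73, 8.89 and 9.59. A fall of matrix genes with diabetes itself also stays open and was not tested on its own.

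The 10 splits of the 6 arrays into 3 and 3, the real one included, are too few to give a share under 0.05. For the 40 genes at the 2-fold threshold, 5 of the 10 splits gave as many, and the highest of the others gave 105. For genes past an adjusted p of 0.05, 10 of 10 gave at least the real 0, which holds by construction and says nothing about chance, and the highest other gave 5. For the 6 lists, 6 of 10 gave as many, with 10 in the highest other, and for the median of the wound-activated list, 1 of 10 reached the real 2.26, with 1.57 in the highest other. All 6 lists were also called in other splits. Diabetic replicates 1 and 2 with non-diabetic replicate 2 gave the cornified envelope, barrier lipid, wound-activated, matrix and mast cell lists. Diabetic replicates 1 and 3 with non-diabetic replicate 2 gave the oxidative stress list. Both splits share 2 diabetic arrays with the real one. A call at the preset correlation thus does not by itself tie a list to diabetes. The split that set diabetic replicates 1 and 2 with non-diabetic replicate 1 against the rest gave the 105 genes, which points to a structure of the samples. Its origin was not tested, and that split shares diabetic replicates 1 and 2 with the real grouping and keeps the pair numbered 1 together. Of the 4 splits that part all 3 same-numbered pairs, the real one gave 40 genes at the 2-fold threshold and the others between 13 and 26, with between 2 and 8 lists.

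In a fit of all 53605 probe sets kept, 174 of the 37519 without a name here met the 2-fold threshold, 73 of them higher in diabetic skin, which was 0.464% of them against 0.242% of the named probe sets. None passed an adjusted p of 0.05 in limma, where the lowest was 0.789.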
